A study of Arabidopsis thaliana with 36 samples.

How the data were processed

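RNA was sequenced from whole Arabidopsis thaliana seedlings of the wild type Col-0 (WT), pif4-2 and hda9-1, grown in short days (8 h light and 16 h dark) at 22 or 27 °C and harvested at lights on at an age of 2 or 7 days. Per the labels, each of the 36 libraries holds RNA combined from 3 separately harvested batches. The labels do not say whether the libraries that carry the same replicate number share batches. Libraries were made with the Illumina TruSeq kit and read on a HiSeq2500 as single reads of 50 bp. The submitters' processing notes name FastQC, TopHat2, Bowtie, HTSeq, DESeq and the genome build TAIR10.

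The deposited files hold 1 signal per gene and library: a read count divided by 1 size factor per library, with 33540 genes and 5 counting categories per file. The authors do not state in the labels which libraries were scaled together or which strand setting was used. The values were tested for a common divisor per library, and whole reads were recovered for 100% of them within 0.01 of a whole number. Reads in genes ranged from 21906850 to 67795235 per library with a median of 44904956. The counting categories held 6.05 to 8.42% of the reads as not uniquely placed, 0.95 to 1.23% as ambiguous and 0.65 to 0.88% outside genes. A value above 0 in at least 1 library was found for 28211 genes. Names were taken from the reference annotation by locus, which matched 32835 of the genes.

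Libraries were grouped by genotype, age and temperature into 12 groups of 3, with no library left out. Differences were tested with limma 3.58.1 in R 4.3.3 (limma-trend with eBayes) on log2(value + 1), with 1 mean per group. Genes with a value of at least 10 in at least 3 libraries were tested. The 18 libraries of each age were fitted together (21164 genes at 2 days and 21320 at 7 days), and all 36 libraries (21879 genes) for the comparisons between ages. A gene was called where the p adjusted by the Benjamini-Hochberg method over all genes tested was under 0.05. The 22 comparisons are the response to temperature of each genotype at each age, each mutant against WT at each temperature and age, the differences of these responses between genotypes at each age, WT at 7 against 2 days at 22 °C, and the difference of the WT response between ages.

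The 18 gene lists cover auxin biosynthesis, auxin response, PIF and shade targets, light and temperature signalling, histone deacetylases and H2A.Z, heat shock, cold response, photosynthesis and chlorophyll, seed storage and maturation, seed reserve mobilisation, circadian clock, flowering time, salicylic acid defence, gibberellin and brassinosteroid metabolism, cell wall expansion, flavonoid and anthocyanin, senescence, and root tissue markers. Of 246 entries 245 were kept, and 1 was dropped because its name and locus did not match. No gene is in more than 1 list. All 10 root markers were tested at each age, so whole seedlings express each of them. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 18 lists of a comparison, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

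The genes that the text could name were set by a fixed rule. PIF4, HDA9, YUC8, IAA19 and IAA29 could always be named. The rule added the 6 largest rises and the 6 largest falls among called genes with a mean of at least 50. In comparisons of 2 groups, but not in differences of responses, these also had to show no overlap between replicates. Up to 4 called members of each list were added, or the 2 with the smallest p where none was called. The text gives part of the genes so set, chosen after the results were seen, and leaves out some of the 5 fixed genes in some comparisons. The groups, comparisons, tests, gene lists, this rule and the alternatives were chosen before the data were examined, except where stated. The part of the response change that pif4 and hda9 share was estimated from the covariance across genes of their 2 differences from WT. The mean covariance in 100 simulations of unchanged groups was subtracted, and the error came from leaving out each library. Each simulation drew library residuals of any group of that age with replacement, for the WT libraries as well. Both mutants shared the drawn WT libraries.

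The alternatives were a pseudocount of 8, no filter on low values, the replicate number as a block, values rescaled with TMM factors, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, only the compared groups in the fit, and each library left out in turn. Fits without the spread of pif4 replicate 3 at 22 °C and 7 days, and without replicate 3 of WT and pif4 at 2 days, were added after seeing the data. A count was taken as moved beyond 1.5 times. Pairing by replicate number was judged from the values and not from the labels. A comparison of 2 groups holds 3 pairs of libraries with the same number, and a difference of responses 18. Numbers were taken as pairing the libraries where deviations from the group means correlated above 0.1 across genes in all such pairs. This held for the response of pif4 at 2 days (lowest correlation 0.196), pif4 minus WT at 22 °C (0.194) and 27 °C (0.236) and hda9 minus WT at 27 °C (0.211) at 2 days, and the response of hda9 at 7 days (0.104). In pif4 minus WT at 22 °C not every library was closest to the one with its own number in the other group. A replicate 3 that stands apart in both groups can alone give such correlations. The block was fitted over all libraries of an age, also where the numbers do not pair. Splits of the libraries were counted, 10 for 3 against 3 libraries and 100 for differences of responses, the real one included in each. For the latter the additive difference between the groups was first removed, because exchanging labels at 1 temperature turns that difference into a difference of responses. The removal was chosen after splits without it were seen, and both versions are given.

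The procedure was tested on simulated data with 200 changed genes. Limma recovered 62.7, 89.6 and 100% of changes of 1.5, 2 and 4 fold for the WT response at 2 days, with 13 false calls among 20712 genes, and 73.1, 88.1 and 100% at 7 days. For the difference of responses between hda9 and WT at 2 days it recovered 35.8, 80.6 and 100%, and for pif4 at 7 days 52.2, 80.6 and 97%. Figures were drawn with matplotlib 3.10.9.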

Results

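Transcript levels were measured by RNA sequencing in Arabidopsis thaliana seedlings of 3 genotypes. These were the wild type Col-0 (WT), pif4-2, a mutant of the gene for the growth-promoting transcription factor PIF4, and hda9-1, a mutant of the gene for the histone deacetylase HDA9. Seedlings grew in short days at 22 or 27 °C and were harvested at dawn at an age of 2 or 7 days, so the values describe 1 time of day. Developmental stage was not assessed apart from age. A difference between temperatures or genotypes at 1 age can therefore include a difference of stage. The 12 groups held 3 libraries each (n = 3 for every group mean, 36 libraries in all), with 21906850 to 67795235 reads assigned to genes per library and a median of 44904956. Values are the deposited read counts divided by a size factor per library, called normalised counts here. Fold changes come from log2(normalised count + 1) and therefore understate changes of genes with low counts. A gene is called higher or lower where the limma p, adjusted by the Benjamini-Hochberg method over all genes tested, lies under 0.05. These p-values measure only the spread between these libraries, each of which holds pooled RNA from 3 harvested batches. No strand setting is stated for the counting, so counts of overlapping or antisense genes can include each other's reads.

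Temperature parted the libraries at each age. Among the 2-day-old seedlings, the first principal component held 71.6% of the variance and placed every 22 °C library at 15.56 or above and every 27 °C library at -35.68 or below. In 7-day-old seedlings it held 58.7%, with the 22 °C libraries at 39.65 or above and the 27 °C libraries at -31.85 or below. The second component, with 11.4% of the variance at 2 days and 10.9% at 7 days, parted the hda9 libraries from WT and pif4. The library pif4 at 22 °C, replicate 3, aged 7 days, lay apart from its 2 group mates on the fourth component (-47.09) and was kept. Replicate 3 of WT and of pif4 stood apart at 2 days: on the first component they lay at 55.75 and 55.74 at 22 °C, against 77.07 to 82.64 for replicates 1 and 2, and at -72.54 and -63.03 at 27 °C, against -43.74 to -35.68. The difference of replicate 3 from the other 2 correlated between WT and pif4 across genes at 0.47 (22 °C) and 0.519 (27 °C), and all 4 libraries were kept. Replicate 3 of hda9 lay on the same side of its group mates, at 15.56 against 42.84 and 22.47 at 22 °C and at -87.99 against -65.39 and -70.59 at 27 °C. Fits with the 4 WT and pif4 libraries left out were added after seeing the data. They keep replicate 3 of hda9, so in them a difference of hda9 from WT or pif4 can include a difference between replicates.

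**Figure D1:**
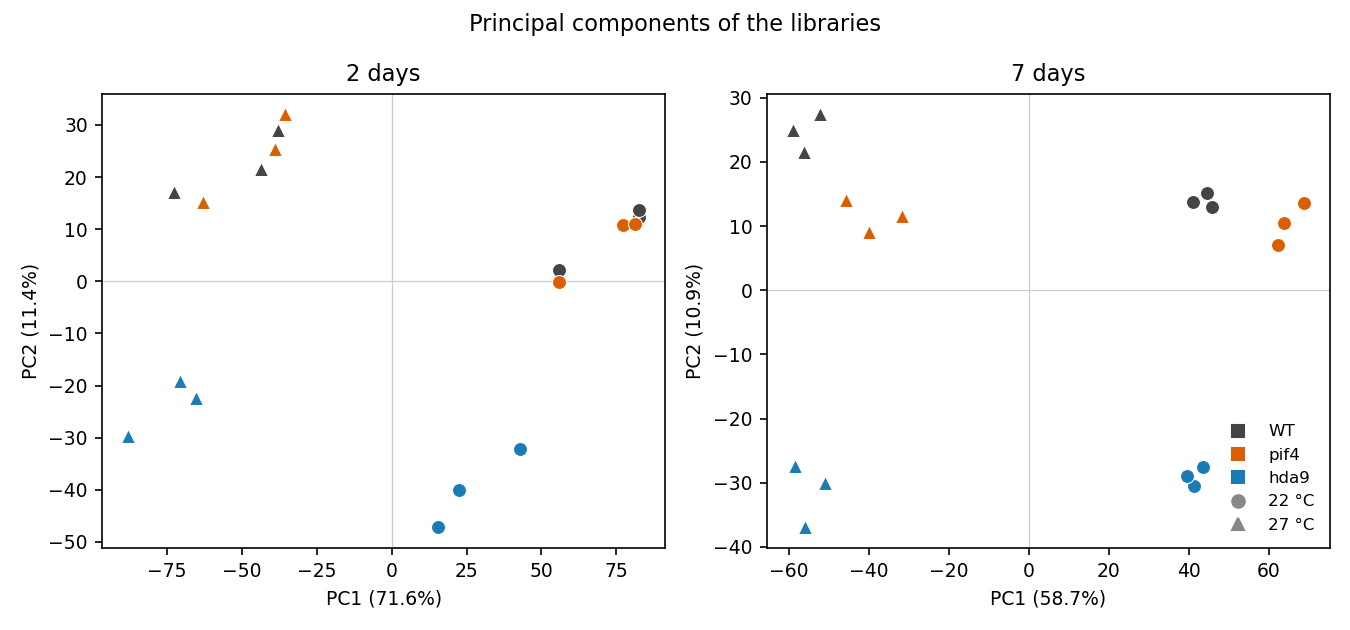
First and second principal components (arbitrary units) of the log2 normalised counts, drawn for each age separately; each point is 1 library, colours mark the genotype and shapes the temperature. Libraries at 22 °C lie at positive values of the first component and libraries at 27 °C at negative values.

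The mutated genes were examined first, because their levels check the labels. HDA9 (AT3G44680) stood at 549 ± 37.9 normalised counts (SD, n = 3) in WT and 26.7 ± 0.83 in hda9 at 22 °C at 2 days. It was lower in hda9 in all 4 comparisons with WT, by log2 fold changes of -4.31 (SE 0.09) and -3.35 (SE 0.09) at 22 and 27 °C at 2 days, and of -3.15 (SE 0.14) and -2.70 (SE 0.14) at 7 days. Reads over the whole PIF4 gene (AT2G43010) were not lower at 2 days in the libraries labelled pif4-2, with log2 differences from WT of 0.87 (SE 0.23, limma adjusted p = 0.437) at 22 °C and -0.04 (SE 0.23, adjusted p = 1) at 27 °C. By the correlation rule the replicate numbers pair the libraries in these comparisons, but at 22 °C not every library was closest to its own number. With the replicate number as a block the adjusted p at 22 °C was 0.000565 (0.000565 to 1 over all alternatives, and 0.0145 with replicate 3 of WT and pif4 left out). That block spans all 18 libraries of this age, and hda9 and WT at 22 °C do not pair (lowest correlation -0.097). At 7 days they were lower, with log2 differences of -0.66 (SE 0.09) and -0.75 (SE 0.09). A gene-level count of an insertion allele can include reads outside the insertion, so PIF4 does not check this label, and the text speaks of libraries labelled pif4-2. Other genes link these libraries across ages and temperatures: 21 genes differed from WT in the same direction in all 4 comparisons, among them the non-coding RNA gene AT2G01422, which was lower by log2 fold changes of -7.12 to -8.45. AT2G01422 was also lower than WT in hda9 in all 4 comparisons, by -3.02 to -3.83. Of the other 20 genes 8 had the same sign in hda9 in all 4 comparisons, with a mean of at least 0.5 of the size. These 9 do not set the pif4-2 libraries apart from both other genotypes by direction alone.

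**Figure D2:**
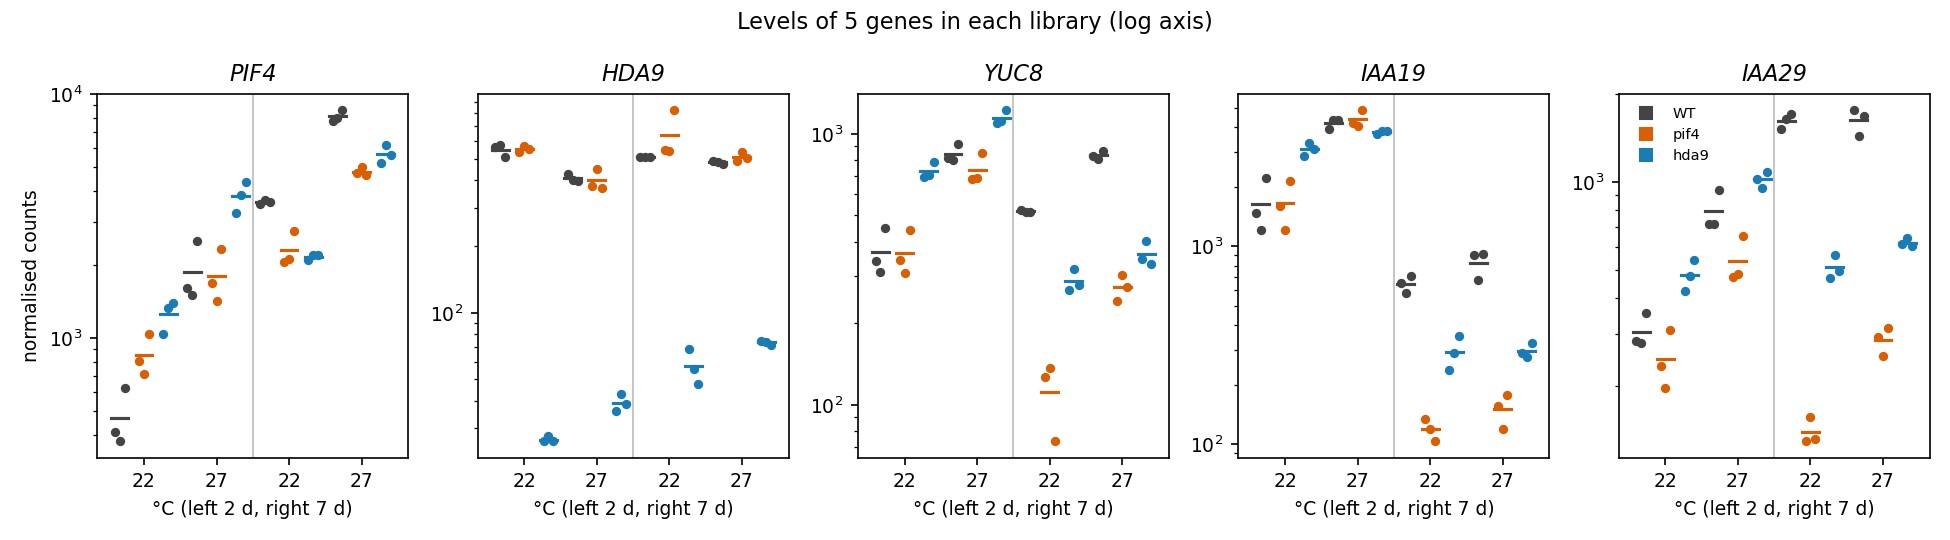
Normalised counts (log axis) of PIF4, HDA9, YUC8, IAA19 and IAA29 in each library; points are libraries, bars are group means of 3 libraries, and the groups are ordered by age, temperature and genotype. HDA9 lies far below the other genotypes in every hda9 group, and among the groups aged 7 days IAA29 lies lowest in the pif4 groups.

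Development between 2 and 7 days was asked of WT at 22 °C. Isocitrate lyase (ICL) and malate synthase (MLS), the glyoxylate cycle enzymes that turn stored oil into sugar, fell by 7.32 (SE 0.39) and 6.56 (SE 0.18) on the log2 scale, and of 13 seed reserve mobilisation genes 12 fell and 1 rose (camera adjusted p = 6.5e-06, but adjusted p = 0.301 with an estimated correlation). PORA, the protochlorophyllide reductase of dark-grown seedlings, fell by 9.52 (SE 0.33), while of 26 photosynthesis and chlorophyll genes 21 rose and 4 fell (camera adjusted p = 0.0238, but adjusted p = 0.562 with an estimated correlation). The light-harvesting gene LHCB2.1 was higher (log2 2.46, SE 0.24). Growth regulators moved as well: PIF4 rose 7.84-fold (log2 2.97, SE 0.18), PIF7 12.9-fold (log2 3.69, SE 0.22) and IAA29 5.32-fold (log2 2.41, SE 0.14), whereas IAA19 fell by 1.29 (SE 0.18). Adjusted over the list alone, 12 reserve mobilisation genes fell and 21 photosynthesis genes rose. In total 16724 of 21879 genes were called, 8337 higher and 8387 lower at 7 days.

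Warmth at 2 days, asked first of WT, raised genes of auxin response, PIF targets and clock genes and lowered anthocyanin genes. PIF4 was 3.96-fold higher at 27 °C (log2 1.99, SE 0.23) and YUC8 (AT4G28720), an enzyme of auxin synthesis, 2.33-fold higher (log2 1.22, SE 0.14). Of 19 auxin response genes 16 rose and 2 fell (16 and 2 adjusted over the list alone). They include the auxin-induced repressors IAA19 (AT3G15540, 2.66-fold, log2 1.41, SE 0.19), IAA29 (AT4G32280, 2.58-fold, log2 1.37, SE 0.16) and IAA6 (8.96-fold, log2 3.16, SE 0.32). Of 14 PIF and shade targets 12 rose and 1 fell (12 and 1 over the list alone), among them the cell wall gene XTH15 (6.16-fold, log2 2.62, SE 0.12). Of 15 clock genes 11 rose and 1 fell (11 and 1 over the list alone), among them GI (6.85-fold, log2 2.78, SE 0.14) and PRR7 (5.90-fold, log2 2.56, SE 0.14). Of 10 flavonoid and anthocyanin genes 8 fell and 1 rose (8 and 1 over the list alone). These include LDOX, which fell by 5.54 on the log2 scale (SE 0.41), DFR, which fell by 4.68 (SE 0.53), and their regulator MYB75, which fell by 3.47 (SE 0.41). The pectin methylesterase gene PME61 rose by log2 5.66 (SE 0.39). With a pseudocount of 8 the log2 changes were -3.48 (LDOX), -2.43 (DFR), -2.20 (MYB75) and 3.61 (PME61). The camera adjusted p was 0.00176 for each of the 3 rising lists and 0.00215 for the anthocyanin list, but with an estimated correlation adjusted p = 0.622 and adjusted p = 0.229.

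Root markers went both ways in warm WT seedlings at 2 days. The root hair genes COBL9 and EXPA7 fell by 2.87 (SE 0.33) and 2.74 (SE 0.45) on the log2 scale, and of the 10 markers 4 fell and 4 rose (4 and 4 adjusted over the list alone, camera adjusted p = 0.89). The whole comparison called 15237 of 21164 genes, 7719 higher and 7518 lower at 27 °C, of which 2069 and 2020 changed at least 2-fold.

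The same question in the mutants at 2 days gave calls in the same 4 lists. In the libraries labelled pif4-2, PIF4 rose 2.09-fold (log2 1.07, SE 0.23), YUC8 2.04-fold (log2 1.03, SE 0.14) and IAA19 2.72-fold (log2 1.44, SE 0.19). Of the auxin response genes 16 rose and 2 fell, of the PIF targets 12 rose and 1 fell, of the clock genes 11 rose and 1 fell, and of the anthocyanin genes 8 fell. Their camera adjusted p were 0.000945, 0.00136, 0.00199 and 0.000945, but with an estimated correlation adjusted p = 0.621 for the first 3 and adjusted p = 0.126 for the last. In hda9, YUC8 rose 1.57-fold (log2 0.65, SE 0.14) and LDOX fell by 6.23 (SE 0.41; log2 -3.62 with a pseudocount of 8), while IAA19 had a log2 difference of 0.29 (SE 0.19, limma adjusted p = 0.177, or 0.00352 with only these 2 groups in the fit, 0.0149 with replicate 3 of WT and pif4 left out, and up to 0.358 in other alternatives). Of 13 heat shock genes 9 rose and 1 fell in hda9, among them the galactinol synthase GOLS1 (6.87-fold, log2 2.78, SE 0.20), with camera adjusted p = 0.00806 but adjusted p = 0.477 with an estimated correlation. Of the auxin response genes 15 rose and 1 fell, and of the PIF targets 8 rose and 1 fell (camera adjusted p = 0.00624 and 0.04, but adjusted p = 0.85 for each with an estimated correlation). The clock list (11 rose, 1 fell) and the anthocyanin list (8 fell) had camera adjusted p = 0.00118 and 0.00119, but adjusted p = 0.471 and adjusted p = 0.137 with an estimated correlation. Limma called 14857 genes in pif4 (7567 higher, 7290 lower) and 14134 in hda9 (6722 higher, 7412 lower).

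**Figure D3:**
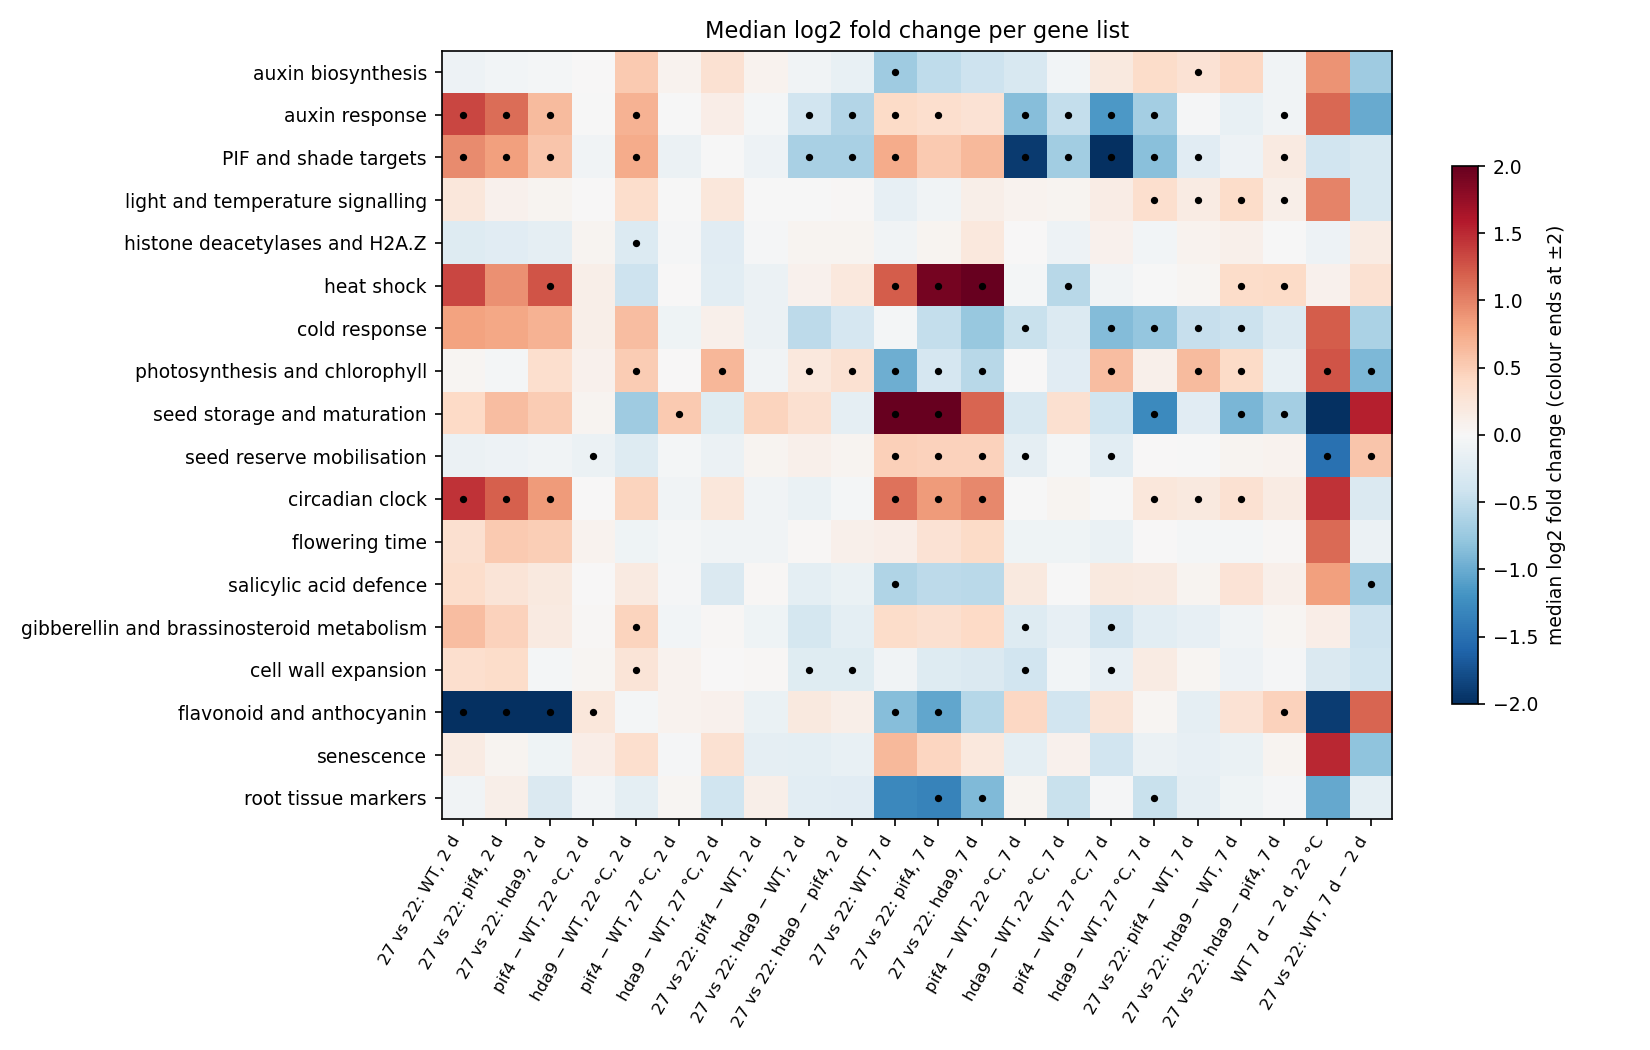
Median log2 fold change of the tested members of the 18 gene lists (one line per list) in the comparisons of the report (one column each); colour gives the median on the log2 scale, and a dot marks a camera adjusted p under 0.05. The PIF and shade targets and the auxin response genes are blue in the 4 mutant comparisons at 7 days and red in the temperature responses of WT at each age.

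At 7 days warmth again raised PIF4 in WT, 2.24-fold (log2 1.17, SE 0.09), and YUC8, 1.61-fold (log2 0.68, SE 0.16), but IAA29 did not pass (log2 0.001, SE 0.10, limma adjusted p = 0.996). IAA19 (log2 0.35, SE 0.16, limma adjusted p = 0.0747) passed with the replicate number as a block (0.0409), with edgeR (0.032), with DESeq2 (0.0273), with only these 2 groups in the fit (0.0231) and without WT replicate 2 at 27 °C (0.0228), and had up to 0.228 in other alternatives. Of 14 heat shock genes 11 rose (11 adjusted over the list alone, with 1 lower), among them the small chaperone HSP17.4 (8.44-fold, log2 3.08, SE 0.22). Of 26 photosynthesis and chlorophyll genes 21 fell and 0 rose (21 over the list alone), including the Rubisco small subunit RBCS1B, which fell by 2.71 (SE 0.14). Genes of seed maturation and seed reserve use were higher in the warmth: 12 of 14 and 11 of 13 rose and 0 fell (12 and 12 over the lists alone), with the oil body protein OLEO2 24.4-fold (log2 4.61, SE 0.46, or 3.21 with a pseudocount of 8) and ICL 6.09-fold (log2 2.61, SE 0.49, or 3.22 without WT replicate 2 at 22 °C) higher. Camera gave adjusted p = 1.74e-05, 2.61e-07, 0.000544 and 0.000136 for these 4 lists, but adjusted p = 0.315 for each with an estimated correlation.

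Growth and defence lists of WT were also called at 7 days. Of 19 auxin response genes 10 rose (camera adjusted p = 0.00936), of 14 PIF targets 9 rose and 2 fell (camera adjusted p = 0.028), of 15 clock genes 9 rose and 4 fell (camera adjusted p = 0.0372), and of 8 auxin synthesis genes 7 fell and 1, YUC8, rose (camera adjusted p = 0.028). Each of these 4 calls was lost with an estimated correlation, with adjusted p = 0.319. Of 12 salicylic acid defence genes 6 fell and 1 rose, among them PR5, which fell by 3.21 (SE 0.52; log2 -1.69 with a pseudocount of 8), and of 7 flavonoid genes 5 fell. Camera adjusted p were 0.0315 and 0.047, but adjusted p = 0.315 and adjusted p = 0.319 with an estimated correlation. Of 10 root markers 6 fell and 0 rose (camera adjusted p = 0.0501, 0.045 after rescaling with TMM factors and 0.0422 with the replicate number as a block, but adjusted p = 0.36 with an estimated correlation), and the root hair gene COBL9 fell by 2.62 on the log2 scale (SE 0.31). Limma called 12229 of 21320 genes, 5604 higher and 6625 lower at 27 °C.

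In the mutants at 7 days, IAA29 rose 2.07-fold in warm pif4-2 libraries (log2 1.05, SE 0.10) and HSP17.6C 20.9-fold in warm hda9 libraries (log2 4.39, SE 0.26, or 3.31 with a pseudocount of 8). Of 14 heat shock genes 13 rose and 1 fell in pif4, and 12 rose in hda9 (camera adjusted p = 2.9e-05 and 5.99e-07, but adjusted p = 0.36 and adjusted p = 0.225 with an estimated correlation). Photosynthesis genes fell in 13 of 26 cases and rose in 1 in pif4, and fell in 16 in hda9 (camera adjusted p = 0.00885 and 9.24e-05, but adjusted p = 0.555 and adjusted p = 0.419 with an estimated correlation). Root markers fell too, 7 of 10 in pif4 and 6 of 10 in hda9 (camera adjusted p = 0.00923 and 0.033, but adjusted p = 0.36 and adjusted p = 0.419 with an estimated correlation). Auxin response genes rose in 11 of 19 cases in pif4 and 5 of 7 flavonoid genes fell (camera adjusted p = 0.00774 and 0.0217, but adjusted p = 0.36 for each with an estimated correlation). Of 13 reserve mobilisation genes 12 rose and 1 fell in pif4 and 12 rose in hda9 (camera adjusted p = 0.000374 and 4.4e-05, but adjusted p = 0.36 and adjusted p = 0.33 with an estimated correlation). Of 14 seed storage and maturation genes 9 rose in pif4 and 7 in hda9, with 0 lower. The list was called in pif4 (camera adjusted p = 0.00774, but adjusted p = 0.36 with an estimated correlation) and not in hda9 (camera adjusted p = 0.0512, and adjusted p = 0.443 with an estimated correlation). Of 15 clock genes 10 rose and 3 fell in pif4, and 11 rose and 2 fell in hda9 (camera adjusted p = 0.00744 and 0.000354, but adjusted p = 0.36 and adjusted p = 0.225 with an estimated correlation). In hda9 8 of the auxin response genes and 9 of the 14 PIF targets rose, with 3 PIF targets lower (camera adjusted p = 0.0763 and 0.0512). Replicate numbers paired the hda9 libraries, and with the replicate number as a block these lists had camera adjusted p = 0.0422 and 0.036, but adjusted p = 0.443 and adjusted p = 0.432 with an estimated correlation and no block. Limma called 12805 genes in pif4 (6072 higher, 6733 lower) and 12344 in hda9 (5861 higher, 6483 lower).

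Whether WT responded to warmth differently at the 2 ages was tested directly, as the response at 7 days minus that at 2 days. The response was lower at 7 days for IAA6 (-3.04, SE 0.41), IAA19 (-1.06, SE 0.26) and IAA29 (-1.37, SE 0.20) on the log2 scale. Of 20 auxin response genes 11 had a lower and 3 a higher response (11 and 3 adjusted over the list alone), but the list was not called (camera adjusted p = 0.0804, and adjusted p = 0.514 with an estimated correlation). PME61, which rose at 2 days, had a difference of -6.42 (SE 0.58; -4.09 with a pseudocount of 8). Among 26 photosynthesis genes 22 had a lower response at 7 days and 0 a higher one (23 lower adjusted over the list alone), among them RBCS1B (log2 -1.73, SE 0.17). Of 13 reserve mobilisation genes 10 had a higher response (12 over the list alone), among them MLS (log2 2.30, SE 0.26). Of 13 salicylic acid defence genes 8 had a lower response (9 over the list alone). Camera adjusted p were 2.38e-06, 1.4e-05 and 0.0262 for these 3 lists, but adjusted p = 0.463, adjusted p = 0.391 and adjusted p = 0.184 with an estimated correlation. Limma called 10377 of 21879 genes, 4545 with a higher and 5832 with a lower response at 7 days.

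What PIF4 contributes was asked by comparing the libraries labelled pif4-2 with WT. At 2 days few genes were called. YUC8 (log2 -0.01, SE 0.14), IAA19 (log2 0.02, SE 0.19) and IAA29 (log2 -0.32, SE 0.16) at 22 °C had limma adjusted p = 1, as did YUC8 (log2 -0.20, SE 0.14) and IAA19 (log2 0.05, SE 0.19) at 27 °C. IAA29 at 27 °C (log2 -0.57, SE 0.16) had adjusted p = 0.603, or 0.00258 with the replicate number, which pairs these libraries, as a block. The non-coding RNA gene AT2G01422 fell by 7.12 (SE 0.40) at 22 °C and by 7.69 (SE 0.40) at 27 °C, and the pseudogene AT5G35935 was higher by log2 4.75 (SE 0.14) and 4.46 (SE 0.14). AT5G35935 was also higher in hda9 than in WT at 2 days (log2 4.08, SE 0.14, at 27 °C). Limma called 39 of 21164 genes at 22 °C (20 higher, 19 lower) and 39 at 27 °C (22 higher, 17 lower). An unadjusted p under 0.05 was found for 674 and 766 genes, fewer than the share of 0.05 that unchanged genes would give. So the few calls do not show that the other genes were unchanged. With only the 2 groups in the fit 24 and 17 genes were called. With replicate 3 of WT and pif4 left out, a setting chosen after seeing the data, 18 were called at 22 °C.

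Lists with no called member at 2 days still had camera calls. At 22 °C these were reserve mobilisation (median log2 -0.11, camera adjusted p = 0.00212) and flavonoids (median log2 0.22, camera adjusted p = 0.0275), but with an estimated correlation adjusted p = 0.893 and adjusted p = 0.522. At 27 °C it was seed storage (median log2 0.52, camera adjusted p = 0.00446), but adjusted p = 0.907 with an estimated correlation. By the correlation rule the replicate numbers paired the libraries in these comparisons, but at 22 °C not every library was closest to its own number. With the replicate number as a block limma called 59 genes at 27 °C, and camera also called the photosynthesis list at 22 °C (adjusted p = 0.0326) and the PIF targets (adjusted p = 0.0121) and reserve mobilisation (adjusted p = 0.0455) at 27 °C, from 0.105, 0.0619 and 0.149 without the block. With an estimated correlation and no block they had adjusted p = 0.893, adjusted p = 0.907 and adjusted p = 0.907.

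At 7 days the growth genes were lower in the libraries labelled pif4-2. YUC8 was 4.75-fold lower at 22 °C (log2 -2.25, SE 0.16) and 3.07-fold lower at 27 °C (log2 -1.62, SE 0.16). IAA19 was 5.42-fold (log2 -2.44, SE 0.16) and 5.51-fold (log2 -2.46, SE 0.16) lower, and IAA29 11.7-fold (log2 -3.55, SE 0.10) and 5.64-fold (log2 -2.50, SE 0.10) lower. Of 14 PIF and shade targets 14 fell at 22 °C and 13 at 27 °C, with 0 higher (14 and 14 adjusted over the list alone). The jasmonate sulfotransferase ST2A was 8.16-fold (log2 -3.03, SE 0.16) and 14.1-fold (log2 -3.81, SE 0.16) lower. Of 19 auxin response genes 15 and 16 fell, with 0 higher (16 and 18 over the list alone). These list calls held with an estimated correlation: camera gave adjusted p = 1.24e-18 and 9.45e-18 for PIF targets and 4.2e-17 and 1.94e-15 for auxin response, and with an estimated correlation adjusted p = 0.00322, 0.00398, 0.00954 and 0.0141.

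Hormone, cold and photosynthesis genes differed as well in these libraries at 7 days. Of 11 gibberellin and brassinosteroid metabolism genes 4 fell at 22 °C and 7 at 27 °C (6 and 8 adjusted over the list alone), with the gibberellin 20-oxidase GA20OX1 changing by -1.28 (SE 0.21) and -1.61 (SE 0.21) on the log2 scale. Of 9 cold response genes 2 and 6 fell (3 and 6 over the list alone), with KIN2 changing by -1.14 (SE 0.18) and -1.56 (SE 0.18). At 27 °C both calls held with an estimated correlation, with camera adjusted p = 1.53e-05 and 0.000558 and adjusted p = 0.0437 and 0.04 with an estimated correlation. At 22 °C camera gave adjusted p = 0.00107 and 0.0204, but adjusted p = 0.134 for each with an estimated correlation. Among 26 photosynthesis genes 17 were higher at 27 °C (19 over the list alone), among them RBCS1B (3.73-fold, log2 1.90, SE 0.14), with camera adjusted p = 1.07e-11 but adjusted p = 0.116 with an estimated correlation. Of 12 cell wall expansion genes 8 fell and 1 rose at 22 °C, and 4 fell at 27 °C, among them the expansin EXPA5, which fell by 0.62 (SE 0.18) at 22 °C and 1.92 (SE 0.18) at 27 °C. The EXPA5 call at 22 °C was lost without WT replicate 2 or 3 or pif4 replicate 2 (adjusted p = 0.0749, 0.104 and 0.0686). The cell wall list had camera adjusted p = 0.000954 and 0.00422, but adjusted p = 0.134 and adjusted p = 0.165 with an estimated correlation. Of 13 reserve mobilisation genes 4 and 5 fell (camera adjusted p = 0.00164 and 0.00321, but adjusted p = 0.387 and adjusted p = 0.308 with an estimated correlation).

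Limma called 3764 of 21320 genes at 22 °C (1696 higher, 2068 lower) and 5297 at 27 °C (2793 higher, 2504 lower) between the libraries labelled pif4-2 and WT at 7 days. At 22 °C the count was 1032 with only these 2 groups in the fit, 2310 without WT replicate 2 at 22 °C, and 2509 without WT replicate 3 at 22 °C.

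What HDA9 contributes was asked by comparing hda9 with WT. A later stage of the hda9 seedlings was not excluded as a source of the differences at 2 days. At 2 days growth genes were higher in hda9 at 22 °C, the temperature at which they are low in WT: PIF4 was 2.71-fold (log2 1.44, SE 0.23), YUC8 2.01-fold (log2 1.01, SE 0.14), IAA19 1.95-fold (log2 0.97, SE 0.19) and IAA29 1.57-fold (log2 0.65, SE 0.16) higher. Of 19 auxin response genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), and of 14 PIF targets 11 rose and 1 fell (11 and 1 over the list alone). Of 26 photosynthesis genes 15 rose and 2 fell (17 and 2 over the list alone), among them LHCB2.1 (2.01-fold, log2 1.01, SE 0.28). Of 11 gibberellin and brassinosteroid genes 9 rose and 1 fell, of 12 cell wall expansion genes 8 rose, and of 8 histone deacetylase and H2A.Z genes, HDA9 included, 5 fell and 1 rose. The camera adjusted p were 0.000232, 0.000954, 0.00562, 0.0123, 0.0123 and 0.0296 for these 6 lists, but with an estimated correlation adjusted p = 0.624, 0.624, 0.661, 0.536, 0.536 and 0.536. Among the single genes with the largest rises at 22 °C were ABCG6 (log2 5.95, SE 0.89) and GPAT5 (log2 4.56, SE 0.80), which act in the suberin layer of roots, and the root iron transporter IRT1 (log2 4.98, SE 0.81). Their sizes depend on the settings. With a pseudocount of 8 ABCG6 had log2 4.27, GPAT5 2.74 and IRT1 2.69. Without WT replicate 1 or 3 ABCG6 had 5.002 and 7.041 and GPAT5 3.897 and 5.38. GPAT5 had 3.901 without hda9 replicate 3, and IRT1 5.63 without WT replicate 1. Of the 10 root markers 2 rose and 0 fell at 22 °C (0 and 0 adjusted over the list alone), with a list median of -0.19 (camera adjusted p = 0.605, and adjusted p = 0.772 with an estimated correlation). At 27 °C 0 rose and 3 fell, with a median of -0.40 (camera adjusted p = 0.109, and adjusted p = 0.926 with an estimated correlation). The 2 that rose were CASP1 (log2 0.42, SE 0.16) and CASP2 (log2 0.39, SE 0.14). Their calls were lost with edgeR (adjusted p = 0.0505 and 0.0514) and without WT replicate 1 or 2 or hda9 replicate 3 at 22 °C (adjusted p up to 0.155), and that of CASP2 also without hda9 replicate 2 (0.0552).

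At 27 °C and 2 days PIF4 was 2.08-fold (log2 1.06, SE 0.23) and YUC8 1.36-fold (log2 0.44, SE 0.14) higher in hda9, while IAA19 (log2 -0.15, SE 0.19, limma adjusted p = 0.559) and IAA29 (log2 0.37, SE 0.16, adjusted p = 0.0948) did not pass. The replicate numbers pair these libraries, and with the replicate number as a block IAA29 had adjusted p = 0.00193 (0.00161 to 0.258 over its alternatives, 0.0345 without WT replicate 3 at 27 °C and 0.00161 with replicate 3 of WT and pif4, but not of hda9, left out). Of 26 photosynthesis genes 18 rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 1.61e-07, but adjusted p = 0.496 with an estimated correlation). The light-harvesting gene LHCB1.1 was 6.40-fold higher (log2 2.68, SE 0.42). Limma called 9663 of 21164 genes at 22 °C (5247 higher, 4416 lower) and 6214 at 27 °C (3038 higher, 3176 lower). The count at 27 °C was 3850 with only the 2 groups in the fit, 4108 and 3817 without WT replicate 1 or 2 at 27 °C, and 3711 without hda9 replicate 3 at 27 °C. Without any of these 3 libraries YUC8 lost its call (adjusted p = 0.0758, 0.084 and 0.095). The auxin response list, at camera adjusted p = 0.0617, had adjusted p = 0.0309 with the block, but adjusted p = 0.926 with an estimated correlation and no block.

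At 7 days the same growth genes were lower in hda9 than in WT. YUC8 was 1.81-fold lower at 22 °C (log2 -0.85, SE 0.16) and 2.32-fold lower at 27 °C (log2 -1.22, SE 0.16), IAA19 2.23-fold (log2 -1.16, SE 0.16) and 2.78-fold (log2 -1.47, SE 0.16) lower, and IAA29 3.19-fold (log2 -1.67, SE 0.10) and 2.62-fold (log2 -1.39, SE 0.10) lower. PIF4 was lower too, 1.67-fold (log2 -0.74, SE 0.09) and 1.43-fold (log2 -0.52, SE 0.09). Of 14 PIF and shade targets 6 fell at 22 °C and 11 at 27 °C (10 and 11 adjusted over the list alone), and of 19 auxin response genes 11 and 14 fell (11 and 15 over the list alone), with 0 higher in either list. Camera gave adjusted p = 1.23e-07 and 1.71e-06 for PIF targets and 5.61e-06 and 7.42e-07 for auxin response, but with an estimated correlation adjusted p = 0.0981, 0.0846, 0.268 and 0.0846.

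Other lists were called in hda9 at 7 days as well. At 22 °C 6 of 14 heat shock genes fell, among them HSP17.6C, which fell by 2.48 (SE 0.26; log2 -1.61 with a pseudocount of 8), with camera adjusted p = 0.00323 but adjusted p = 0.468 with an estimated correlation. At 27 °C 9 of 13 light and temperature signalling genes rose and 2 fell, including the bZIP gene HYH (log2 1.07, SE 0.15), and 7 of 15 clock genes rose, including the morning gene CCA1 (2.11-fold, log2 1.08, SE 0.08). Also at 27 °C 6 of 9 cold response genes, 8 of 14 seed storage genes and 3 of 10 root markers fell, among them COR15A, which fell by 1.67 (SE 0.33; log2 -0.62 with a pseudocount of 8), and OLEO2, which fell by 2.06 (SE 0.46; log2 -1.42 without hda9 replicate 3 at 27 °C). Camera gave adjusted p = 0.00302, 0.000846, 0.00302, 0.00327 and 0.0324 for these 5 lists, but with an estimated correlation adjusted p = 0.0846, 0.106, 0.0846, 0.42 and 0.46. Limma called 4273 of 21320 genes at 22 °C (2097 higher, 2176 lower) and 7309 at 27 °C (3929 higher, 3380 lower). At 22 °C the count was 6639 with only these 2 groups in the fit.

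**Figure D4:**
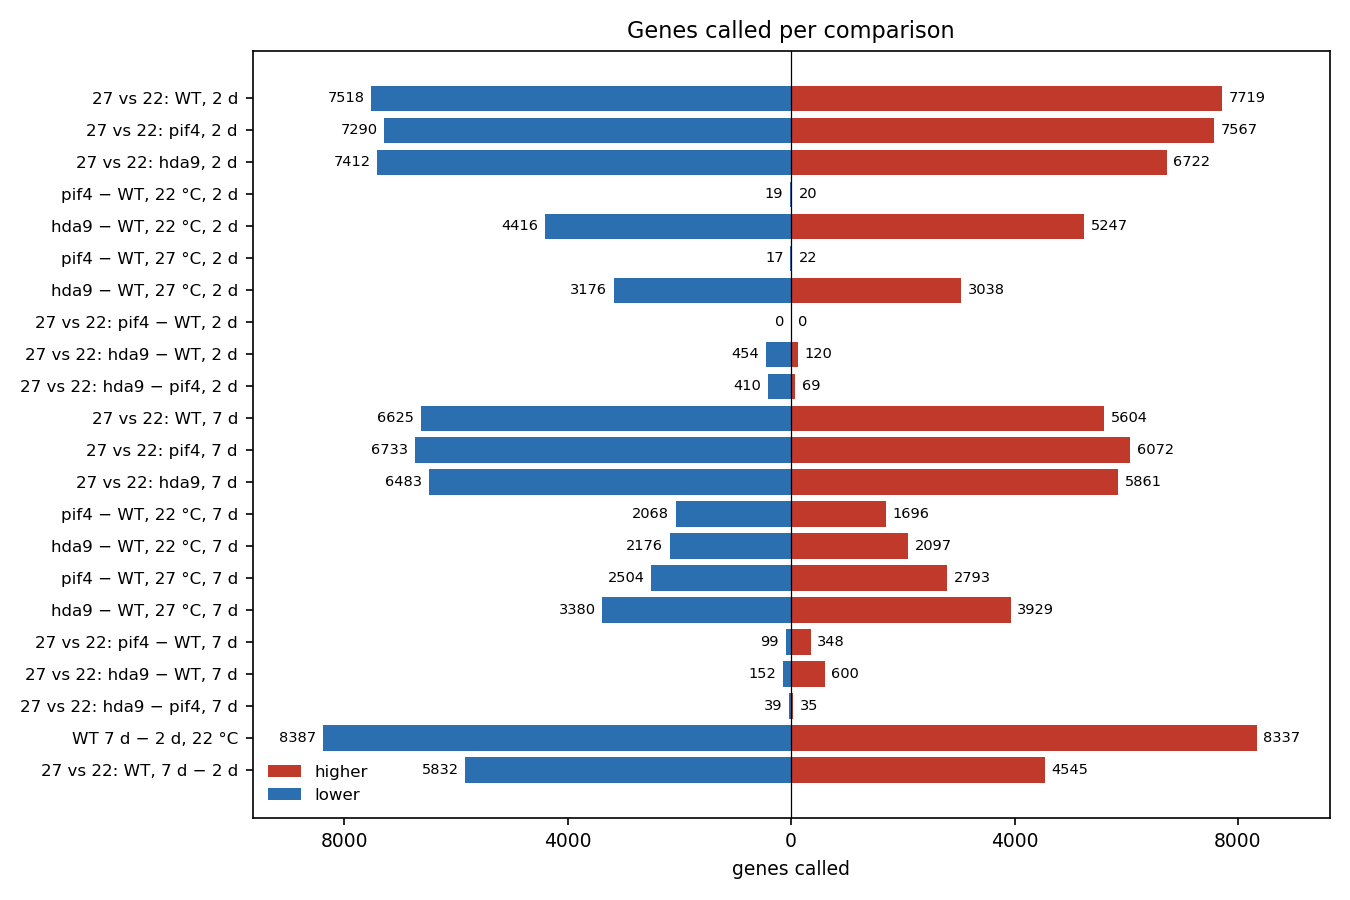
Numbers of genes called higher (right) and lower (left) by limma in each of the 22 comparisons; the axis is linear. The comparison of ages calls the most genes, and the comparisons of pif4 with WT at 2 days call 39 each.

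Whether a mutation changes the response to warmth was tested as the difference of responses. For pif4 against WT at 2 days no gene passed: limma called 0 of 21164 genes, 313 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 3. Where the spread is set well, unchanged genes give a share of about 0.05 under that limit. The 313 genes are fewer, so the test was conservative here and cannot show that the response was unchanged. The difference was -0.92 for PIF4 (SE 0.32, adjusted p = 1) and 0.03 for IAA19 (SE 0.26, adjusted p = 1) on the log2 scale. Limma called 1 gene without pif4 replicate 1 at 22 °C. After rescaling with TMM factors camera called the seed storage list (median 0.44, camera adjusted p = 0.0416).

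For hda9 at 2 days the response to warmth was lower than in WT for 5 named genes. A lower response can come from a higher level at 22 °C. For IAA19 the log2 difference of hda9 from WT was 0.97 at 22 °C and -0.15 at 27 °C (limma adjusted p = 0.559). After rescaling with TMM factors the median differences at 22 and 27 °C were 0.73 and 0.007 for PIF targets and 0.67 and 0.15 for auxin response. The differences of response were -1.12 for IAA19 (SE 0.26, limma adjusted p = 0.0385), -2.32 for IAA6 (SE 0.46), -1.36 for ST2A (SE 0.28), -0.90 for the expansin EXPA5 (SE 0.17) and -2.86 for PME61 (SE 0.55; -1.28 with a pseudocount of 8). The IAA19 call was lost with edgeR (adjusted p = 0.0575) and without any single library but WT replicate 3 and hda9 replicate 1 at 22 °C (adjusted p up to 0.116). The calls of IAA6 and PME61 were lost without WT replicate 1 or hda9 replicate 2 or 3 at 22 °C or hda9 replicate 3 at 27 °C, and that of EXPA5 without WT replicate 1 or 2 or hda9 replicate 3 at 22 °C or hda9 replicate 3 at 27 °C (adjusted p up to 0.0634, 0.0586 and 0.055). ST2A lost its call without WT replicate 1 or 2 at 22 °C or hda9 replicate 2 or 3 at 22 or 27 °C (adjusted p up to 0.0763). Of 14 PIF targets 3 had a lower and 1 a higher response (11 and 1 adjusted over the list alone), of 19 auxin response genes 2 a lower and 1 a higher one (6 and 2 over the list alone), and of 12 cell wall expansion genes 4 a lower one (7 lower and 1 higher over the list alone). None of the 26 photosynthesis genes passed, but their median was 0.21. Camera gave adjusted p = 0.000136, 0.0216, 0.0174 and 0.0174 for these 4 lists, but adjusted p = 0.71 for each with an estimated correlation. Limma called 574 of 21164 genes, 120 higher and 454 lower (20.9% higher), and 304 by edgeR and 1032 by DESeq2. After rescaling with TMM factors it called 371, of which 34% were higher, and with only the 4 groups in the fit 182. With replicate 3 of WT and pif4, but not of hda9, left out, a setting chosen after seeing the data, it called 2092. This count rested on single libraries: it was 68, 74 and 1841 without WT replicate 1, 2 or 3 at 22 °C, 990, 113 and 116 without hda9 replicate 1, 2 or 3 at 22 °C, 202 and 180 without WT replicate 1 or 2 at 27 °C, and 179 and 98 without hda9 replicate 2 or 3 at 27 °C.

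Against pif4 instead of WT, the response of hda9 at 2 days was again lower for IAA19 (difference -1.15, SE 0.26), EXPA5 (-1.15, SE 0.17), GA20OX1 (-1.04, SE 0.18) and PME61 (-3.84, SE 0.55; -1.62 with a pseudocount of 8 and -5.94 with DESeq2). The IAA19 call was lost without any single library but pif4 replicate 3 and hda9 replicate 1 at 22 °C (adjusted p up to 0.0896). Of 14 PIF targets 3 had a lower and 1 a higher response (10 and 1 adjusted over the list alone), of 12 cell wall genes 4 a lower one and of 19 auxin response genes 2 a lower and 1 a higher one. Camera adjusted p were 0.00081, 0.00192 and 0.0189, but adjusted p = 0.734, adjusted p = 0.551 and adjusted p = 0.734 with an estimated correlation. The photosynthesis list (0 called, median 0.30) had camera adjusted p = 0.00168, but adjusted p = 0.734 with an estimated correlation. Limma called 479 of 21164 genes, 69 higher and 410 lower (14.4% higher, or 25.1% after rescaling with TMM factors), and DESeq2 902, and 1021 were called with replicate 3 of WT and pif4, but not of hda9, left out. Without single libraries it called 152 and 156 (pif4 replicate 1 or 2 at 22 °C), 155 and 213 (hda9 replicate 2 or 3 at 22 °C), 224 and 235 (pif4 replicate 2 or 3 at 27 °C) and 247 and 164 (hda9 replicate 2 or 3 at 27 °C).

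At 7 days the response to warmth in the libraries labelled pif4-2 was higher than in WT for IAA29 (difference 1.05, SE 0.14, limma adjusted p = 0.0011), the auxin synthesis gene YUC9 (1.48, SE 0.22) and RBCS1B (1.45, SE 0.20), and lower for XTH15 (-1.59, SE 0.34) and EXPA5 (-1.31, SE 0.25). Of 26 photosynthesis genes 5 had a higher response (16 adjusted over the list alone) (camera adjusted p = 5.18e-14, but adjusted p = 0.25 with an estimated correlation). Of 14 PIF targets 2 had a lower response (4 over the list alone, camera adjusted p = 0.00482, but adjusted p = 0.298 with an estimated correlation). Single members passed in 4 further lists, RVE4 of the clock (higher), YUC9 of auxin synthesis (higher), SPA1 of light signalling (higher) and ERD10 of cold response (lower), with camera adjusted p = 0.0363, 0.0278, 0.0278 and 0.0278, but with an estimated correlation adjusted p = 0.387, 0.359, 0.25 and 0.25. RVE4 lost its call with only the 4 groups in the fit (adjusted p = 0.0776) and without WT replicate 2 at 22 or 27 °C (0.065 and 0.0601), and XTH15 without WT replicate 2 or 3 at 22 °C, WT replicate 2 at 27 °C or pif4 replicate 1 or 3 at 27 °C (up to 0.0642). Limma called 447 of 21320 genes, 348 higher and 99 lower, and DESeq2 894. With only the 4 groups in the fit limma called 184, and without single libraries 205 and 243 (WT replicate 2 or 3 at 22 °C), 768 (pif4 replicate 3 at 22 °C), 221 (WT replicate 2 at 27 °C), and 225 and 269 (pif4 replicate 1 or 3 at 27 °C).

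For hda9 at 7 days the response was higher than in WT for light signalling genes. Of 13 light and temperature signalling genes 5 had a higher and 0 a lower response (8 adjusted over the list alone), among them HYH (0.96, SE 0.22) and PIF7 (0.57, SE 0.15), and this list call held with an estimated correlation (camera adjusted p = 2.17e-05, and adjusted p = 0.0392 with an estimated correlation). Of 26 photosynthesis genes 7 had a higher response (10 over the list alone), among them RBCS1B (1.57, SE 0.20), of 15 clock genes 5, among them CCA1 (0.63, SE 0.11), and of 14 heat shock genes 3, among them HSP17.6II (2.43, SE 0.51; 1.60 with a pseudocount of 8). OLEO2, whose warm rise was smaller (-3.23, SE 0.66; -2.25 with a pseudocount of 8 and -2.59 without hda9 replicate 3 at 27 °C), was 1 of 14 seed storage genes with a lower response, and KIN2 (-0.94, SE 0.25) 1 of 9 cold response genes. KIN2 lost its call without the filter on low values (adjusted p = 0.0689) and without any single library but WT replicate 2 and hda9 replicate 2 at 27 °C (up to 0.143). PIF7 lost its call without the filter (adjusted p = 0.0575), after TMM rescaling (0.0548), with edgeR (0.0602) and without any single library but hda9 replicate 2 at 22 °C and WT replicate 1 at 27 °C (up to 0.111). HYH lost its call without WT replicate 2 at 22 or 27 °C, hda9 replicate 2 at 22 °C, or hda9 replicate 1 or 3 at 27 °C (up to 0.0677). Camera gave adjusted p = 2.83e-08, 0.000359, 0.00122, 0.00529 and 0.0081 for these 5 lists, but with an estimated correlation adjusted p = 0.271, 0.14, 0.312, 0.406 and 0.14. Limma called 752 of 21320 genes, 600 higher and 152 lower, and DESeq2 1173. With only the 4 groups in the fit it called 1493, and 1762 with pif4 replicate 3 at 22 °C left out of the shared spread, a setting chosen after seeing the data. Without single libraries it called 410 and 441 (WT replicate 2 or 3 at 22 °C), 434, 402 and 470 (hda9 replicate 1, 2 or 3 at 22 °C), 432 (WT replicate 2 at 27 °C), and 384 and 328 (hda9 replicate 1 or 3 at 27 °C).

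The mutants' own responses at 7 days differed in few genes. IAA29 had a lower response in hda9 than in pif4 (difference -0.77, SE 0.14, limma adjusted p = 0.0289, or 0.0923 with only the 4 groups in the fit and up to 0.0932 without pif4 replicate 1 or hda9 replicate 2 or 3 at 22 °C or replicate 1 or 3 of pif4 or hda9 at 27 °C), and the nicotianamine synthase NAS2 a higher one (2.51, SE 0.36). Of 19 auxin response genes 1, IAA29, had a lower response, and 0 of 14 heat shock genes, 0 of 14 PIF targets and 0 of 7 flavonoid genes passed, with medians of 0.38, 0.19 and 0.47. Camera adjusted p were 0.0391, 0.00547, 0.0231 and 0.0132, but adjusted p = 0.656 for the first and adjusted p = 0.527 for the others with an estimated correlation. Light signalling (0 of 13) and seed storage (0 of 14) had camera adjusted p = 0.042 each, but adjusted p = 0.527 and adjusted p = 0.656 with an estimated correlation. After rescaling with TMM factors the auxin response, light signalling and seed storage calls were lost (adjusted p = 0.0656, 0.0656 and 0.0866). Limma called 74 of 21320 genes, 35 higher and 39 lower (47.3% higher, or 36.3% after rescaling with TMM factors), DESeq2 334, and limma with only the 4 groups 24. Leaving out single libraries gave 40 and 242 (pif4 replicate 1 or 3 at 22 °C), 33, 20 and 18 (hda9 replicate 1, 2 or 3 at 22 °C), 28, 23 and 28 (pif4 replicate 1, 2 or 3 at 27 °C), and 36 and 22 (hda9 replicate 1 or 3 at 27 °C).

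Whether the 2 mutations change the response to warmth in the same way was asked from the differences of response of pif4 and of hda9, which share their WT libraries. At 7 days RBCS1B (1.45, SE 0.20, in pif4 and 1.57, SE 0.20, in hda9) and EXPA5 (-1.31, SE 0.25, and -1.30, SE 0.25) were among 182 genes with a higher and 38 with a lower response in both, and 0 genes went opposite ways. Independent lists of these sizes would share 9.79 and 0.71 genes. These numbers leave out the shared WT libraries. In 20 draws of unchanged groups 0 genes were called in both, but at most 1 was called in either, so the draws set no expectation for this overlap. The covariance of the differences across 21320 genes was 0.0677. In 100 simulations of unchanged groups it was 0.0334 on average (-0.0026 to 0.094), a range that holds the observed value. Each simulation filled all libraries, those of WT included, with residuals drawn from any group of that age. The 2 mutants shared the drawn WT libraries, which are not the actual ones. The observed covariance exceeded the simulated average by 0.0343 (jackknife SE 0.0147). The draws include pif4 replicate 3 at 22 °C, whose log2 deviation had an SD across genes of 0.473, against 0.24 to 0.306 in the libraries of other groups. The simulated average and range can therefore be larger than the actual WT libraries would give. So a shared part beyond the shared controls was not shown, and these simulations cannot exclude one. The correlation across genes, which are not independent replicates, was 0.566 and the simulated one 0.45 (-0.059 to 0.791). At 2 days the difference of covariances was 0.0065 (SE 0.0475, correlation 0.434 against 0.447), smaller than its error. Because limma called 0 genes for pif4 at 2 days, an overlap could not be counted there. With 3 WT libraries per temperature the controls cannot be split into 2 sets of 2 or more, so how much of the excess comes from the shared controls stays open.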

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

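The tests of GC content in the library that stood apart, of a later stage of hda9, of linkage and of the WT libraries in the pif4 comparisons, and the splits with the additive difference removed were chosen after the results were seen.

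Each result here is a difference between groups that was tested itself. The response of WT to warmth differed between ages in 10377 genes, with differences of -3.04 for IAA6, -1.06 for IAA19, -1.37 for IAA29, -6.42 for PME61, -1.73 for RBCS1B, 2.30 for MLS, -2.61 for NAP and -2.55 for SAG113 on the log2 scale. Its lists with a called difference had medians of -0.90 (photosynthesis), 0.56 (seed reserve mobilisation) and -0.72 (salicylic acid defence), but these calls were lost with an estimated correlation (adjusted p = 0.463, 0.391 and 0.184). The response of hda9 at 2 days differed from that of WT in 574 genes, with -1.12 for IAA19, -2.32 for IAA6, -1.36 for ST2A, -0.90 for EXPA5 and -2.86 for PME61, and with list medians of -0.39 (auxin response), -0.64 (PIF targets), 0.21 (photosynthesis) and -0.24 (cell wall expansion), whose calls were lost with an estimated correlation (adjusted p = 0.71 each). It differed from that of pif4 in 479 genes, with -1.15 for IAA19, -1.15 for EXPA5, -1.04 for GA20OX1 and -3.84 for PME61, and with list medians of -0.58 (auxin response), -0.65 (PIF targets), 0.30 (photosynthesis) and -0.24 (cell wall expansion), lost likewise (adjusted p = 0.551 for cell wall expansion and 0.734 for the others).

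At 7 days the response of pif4 differed from that of WT in 447 genes, with 1.05 for IAA29, 1.48 for YUC9, 1.45 for RBCS1B, -1.59 for XTH15, -1.31 for EXPA5, 0.45 for RVE4, 0.42 for SPA1 and -0.65 for ERD10. Its list medians were 0.29 (auxin biosynthesis), -0.22 (PIF targets), 0.16 (light signalling), -0.45 (cold response), 0.64 (photosynthesis) and 0.20 (clock), and each call was lost with an estimated correlation (adjusted p = 0.25 to 0.387). The response of hda9 differed from that of WT in 752 genes, with 0.96 for HYH, 0.57 for PIF7, 1.57 for RBCS1B, 0.63 for CCA1, 2.43 for HSP17.6II, -3.23 for OLEO2, -0.94 for KIN2 and -1.30 for EXPA5. Its list medians were 0.37 (light signalling), 0.37 (heat shock), -0.43 (cold response), 0.38 (photosynthesis), -0.92 (seed storage) and 0.31 (clock); with an estimated correlation the light signalling call held (adjusted p = 0.0392) and the others were lost (adjusted p = 0.14 to 0.406). The responses of hda9 and pif4 differed in 74 genes, with -0.77 for IAA29 and 2.51 for NAS2, and with list medians of -0.077 (auxin response), 0.19 (PIF targets), 0.12 (light signalling), 0.38 (heat shock), -0.68 (seed storage) and 0.47 (flavonoid), all lost with an estimated correlation (adjusted p = 0.527 to 0.656).

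Replicate 3 of pif4 at 22 °C and 7 days stood apart from its group mates, with an SD across genes of the log2 deviation of 0.473 against 0.24 to 0.306 in the 15 libraries of other groups. GC content and gene length explained 5.6% of its variance across genes, against up to 5.2% in those libraries, which argues against them as the cause. A wrong label of WT as pif4, or of 27 as 22 °C, is argued against as well. On 26 genes chosen at 2 days the library lay at 1.066 on the way from WT (0) to its group mates (1), and on genes called for temperature in WT at 0.016 from 22 °C (0) to 27 °C (1). A swap or mixing with hda9 or with the other age was not tested. What sets the library apart was not found, and no biological explanation was tested.

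Hda9 differed from WT at 2 days in 9663 genes at 22 °C and 6214 at 27 °C. With all libraries thinned to 30599045 reads, 8885 genes were called at 22 °C, and after a trend in GC content and length was removed 9777, against 9663 before, which argues against depth and such a trend as the whole cause. A later developmental stage of the hda9 seedlings stays open. Across genes (not independent replicates) hda9 minus WT correlated with replicate 3 minus replicates 1 and 2 of pif4. The values were 0.57 at 22 °C and 0.408 at 27 °C. At 22 °C that replicate difference also correlated with the response of WT to warmth at 2 days (0.534). Hda9 minus WT itself correlated with the response of pif4 to warmth at 2 days, at 0.553 at 22 °C and 0.248 at 27 °C. So stage and warmth cannot be told apart by these values, and no test placed replicate 3 at a later stage. An advanced stage of hda9 was neither shown nor excluded, and a staged series would have to test it.

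In the libraries labelled pif4-2, 21 genes differed from WT the same way at each age and temperature (9 higher, 12 lower). Linkage to the insertion in PIF4 is argued against for the set as a whole: 1 gene lay within 200 genes of PIF4, where 0.27 are expected, and 4 lay on its chromosome. A difference carried by the WT libraries stays open for part of the set, because 8 of the 21 genes had the same sign against WT in hda9 in all 4 comparisons, with a mean of at least 0.5 of the size. Whether each differed in hda9 was not asked by this count, and AT5G35940, 1 of the 8, had -0.063 at 22 °C and 2 days. No other biological explanation was tested.

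The 6 libraries of 2 groups can be split 3 against 3 in 10 ways, the real one included, which is too few for a share under 0.05. In each of the 15 comparisons of this kind 1 split, the real one, gave a count as large. Every other split mixes the 2 groups, so their real difference adds to the spread within its sets. Low counts in the other splits are therefore largely fixed in advance where that difference is large, and no conclusion on chance is drawn from them. The real counts and the highest of the other splits were 15237 and 0 (WT), 14857 and 0 (pif4) and 14134 and 0 (hda9) for the responses at 2 days, and 12229, 12805 and 12344, each with 0, at 7 days. For pif4 against WT they were 39 and 0 at 22 °C and 39 and 1 at 27 °C at 2 days, and 3764 and 1, and 5297 and 0, at 7 days. For hda9 against WT they were 9663 and 0, and 6214 and 1, at 2 days, and 4273 and 0, and 7309 and 0, at 7 days. For WT at 7 against 2 days they were 16724 and 0. In the 5 comparisons whose replicate numbers pair the libraries by the rule, the other splits, whether they part all 3 pairs or fewer, called 1 gene or none. The same limit holds for these counts.

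For the differences of responses, 100 splits were used, the real one included, with the additive difference between the groups removed. With it, 2 splits gave at least the real count of 574 for hda9 minus WT at 2 days, and 1 split, the real one, did for hda9 minus pif4 at 2 days (479, highest other 385), pif4 minus WT at 7 days (447, 1), hda9 minus WT at 7 days (752, 22), hda9 minus pif4 at 7 days (74, 15) and the WT response between ages (10377, 7341). For hda9 minus WT at 2 days another split called 2616 genes, several times the real count, which points to a structure of the samples that was not identified. Without the removal, 8, 8, 9, 5, 11 and 13 splits were as large for the first 6 in this order (highest others 9474, 3885, 3850, 8967, 9703 and 17589), so whether chance can be excluded rests on a removal chosen after these values were seen, and it is left open for all 6. For pif4 minus WT at 2 days the real count was 0, which all 100 splits must reach (highest other 1), so they say nothing about chance.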

How the results depend on the processing

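The 22 counts of called genes stayed within 1.5 times under a pseudocount of 8 and without the filter on low values. Of 143 named values that passed the test, 127 kept direction and call in every alternative run for them. Sizes were less stable: a pseudocount of 8 moved 14 of the 143 log2 changes by over 1.5 times and DESeq2 moved 1, and leaving out 1 library moved none on the log2 scale but 11 as fold changes (ABCG6, GPAT5, IRT1, DFR, OLEO2 and ICL in 2 comparisons each, and AT2G01422 in 3). The named values were chosen after the main results were seen; 3 that lost calls (ST2A, PIF7 and EXPA5) were taken out of a draft for that reason and then put back. The estimated correlation was the alternative that ended most list calls: 7 of 100 remained, 110 lists were called with the replicate number as a block and 102 after TMM rescaling. Calls after TMM rescaling that are not given above include 1 for histone deacetylases and H2A.Z in the response of hda9 minus pif4 at 2 days (camera adjusted p = 0.0454). Another was photosynthesis in hda9 minus WT at 27 °C and 7 days (camera adjusted p = 0.0453). The mutated genes were lower in 6 of 8 comparisons in each alternative. The cause of the changes below was not tested, except that leaving out a library or groups leaves fewer libraries.

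With the replicate number as a block the counts were 59 for pif4 minus WT at 27 °C and 2 days, and for the differences of responses 2964 (hda9 minus WT) and 2318 (hda9 minus pif4) at 2 days and 780 (pif4 minus WT), 1200 (hda9 minus WT) and 199 (hda9 minus pif4) at 7 days. In these 5 differences of responses the replicate numbers do not pair the libraries by the rule, which asks all 18 pairs. At 2 days the median correlations were 0.222 (hda9 minus WT, lowest -0.14) and 0.216 (hda9 minus pif4, lowest -0.126). At 7 days the medians were 0.054, 0.119 and 0.116. So replicate numbers can still carry part of the spread there. Where the replicate numbers pair, the block changed no call of a list or named value beyond those in the report. DESeq2 called 3, 1032 and 902 genes in the differences of responses of pif4 minus WT, hda9 minus WT and hda9 minus pif4 at 2 days, and 894, 1173 and 334 at 7 days. For hda9 minus WT at 2 days edgeR called 304, and 371 were called after TMM rescaling. With only the compared groups in the fit the counts were 24 and 17 for pif4 minus WT at 22 and 27 °C at 2 days, 3850 for hda9 minus WT at 27 °C at 2 days, 1032 and 6639 for pif4 and hda9 minus WT at 22 °C at 7 days, 182 for the response of hda9 minus WT at 2 days, and 184, 1493 and 24 for the responses of pif4 minus WT, hda9 minus WT and hda9 minus pif4 at 7 days. Without pif4 replicate 3 at 22 °C in the shared spread, a setting chosen after seeing the data, the response of hda9 minus WT at 7 days had 1762, and the other 7 counts stayed within 1.5 times. With replicate 3 of WT and pif4, but not of hda9, at 2 days left out, also chosen after seeing the data, the count was 18 for pif4 minus WT at 22 °C and 2 days. For the differences of responses at 2 days it was 2092 (hda9 minus WT) and 1021 (hda9 minus pif4). The other 9 counts stayed within 1.5 times. In this setting IAA19, which did not pass, turned to -0.002 in pif4 minus WT at 27 °C and to -0.057 in the response of pif4 minus WT at 2 days.

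Leaving out 1 library gave 3711 to 7344 genes for hda9 minus WT at 27 °C and 2 days, 2310 to 4336 for pif4 minus WT at 22 °C and 7 days, and for the differences of responses 0 to 1 (pif4 minus WT), 68 to 1841 (hda9 minus WT) and 152 to 682 (hda9 minus pif4) at 2 days, and 205 to 768, 328 to 1035 and 18 to 242 at 7 days. The shared change of pif4 and hda9 ranged from -0.0122 to 0.0366 at 2 days, where its sign turned, and from 0.0235 to 0.0373 at 7 days. Over genes called in either mutant it was 0.0695 and 0.2255. These genes were chosen by the same differences from the same WT libraries, so larger values can follow from the choice alone. The sign turned without single libraries in 6 named values that did not pass the test: YUC8 (-0.16 to 0.15) and IAA19 (-0.19 to 0.26) in pif4 minus WT at 22 °C and 2 days, PIF4 (-0.24 to 0.18) and IAA19 (-0.028 to 0.107) at 27 °C, IAA29 in the response of WT at 7 days (-0.061 to 0.089), and IAA19 in the response of pif4 minus WT at 2 days (-0.21 to 0.24). With these depths, changes of 1.5 fold were recovered for 35.8 to 73.1% of simulated genes, all drawn above a minimum mean and with no library that stood apart.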

Other observations

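Lists without a camera call in WT held single genes with large changes. Of the senescence genes, the phosphatase SAG113 was 9.55-fold (log2 3.26, SE 0.38, n = 3 per group) and the NAC factor NAP 9.23-fold (log2 3.21, SE 0.36) higher in warm 2-day-old WT seedlings, while SAG29 fell by 2.33 (SE 0.40). Of 7 senescence genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.334, and adjusted p = 0.77 with an estimated correlation). The responses of NAP and SAG113 were lower at 7 than at 2 days, by log2 differences of -2.61 (SE 0.43) and -2.55 (SE 0.47). At 7 days 4 of 6 rose and 1 fell in the warmth (camera adjusted p = 0.299, and adjusted p = 0.36 with an estimated correlation). Between 2 and 7 days ORE1, a NAC factor of leaf ageing, rose 18.3-fold (log2 4.19, SE 0.38) and SAG113 17.7-fold (log2 4.15, SE 0.33), and SAG29 fell by 5.30 (SE 0.49). The list had 5 higher and 2 lower of 7 (camera adjusted p = 0.124, and adjusted p = 0.543 with an estimated correlation).

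The floral repressors SVP and FLC rose with warmth in WT, SVP 2.14-fold (log2 1.095, SE 0.16) at 2 days and 2.09-fold (log2 1.07, SE 0.11) at 7 days, and FLC 1.76-fold (log2 0.81, SE 0.12) and 2.01-fold (log2 1.01, SE 0.10). Of 9 flowering time genes 5 rose at 2 days, and 4 rose and 2 fell at 7 days (camera adjusted p = 0.23 and 0.36, and adjusted p = 0.622 and adjusted p = 0.365 with an estimated correlation). SVP was 8.62-fold higher at 7 than at 2 days (log2 3.11, SE 0.14), with 7 of 10 flowering genes higher and 2 lower (camera adjusted p = 0.067, and adjusted p = 0.301 with an estimated correlation). HTA11 and HTA8, which encode the histone variant H2A.Z, had log2 changes in warm WT seedlings of -0.61 (SE 0.06) and -0.61 (SE 0.09) at 2 days and of -1.19 (SE 0.14) and -0.77 (SE 0.15) at 7 days. Of the 8 histone deacetylase and H2A.Z genes 2 rose and 6 fell at 2 days, and 3 rose and 2 fell at 7 days (camera adjusted p = 0.334 and 0.953, and adjusted p = 0.622 and adjusted p = 0.954 with an estimated correlation). HTA11 and HTA8 were the 2 that fell at 7 days, so HTA9, another H2A.Z gene of the list, was not called lower there. ICS1, the enzyme of salicylic acid synthesis, fell by 1.62 (SE 0.07) in warm WT seedlings at 7 days.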
